A study of Mus musculus with 15 samples.

How the data were processed

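Total RNA of whole hearts was extracted with an RNeasy kit, labelled with biotin and hybridised by standard Affymetrix procedures, per the labels' protocols. The deposited values are intensities, 1 signal per probe set and array, which the submitters' processing notes credit to GCRMA; no version is given in the sources used here. The table did not look like GCRMA output. Its values were linear with 1 decimal, from 0.1 to 80754.9, and the mean after trimming 2% of the values at each end was exactly 250.0 on every array, as in signals scaled to a common target. Signals of weak probe sets scattered widely, which makes large fold changes between weak signals common and limits the power of the test there. How the signals were summarised from probes therefore stays open. Detection calls, scanner files and scan dates were not used here, so no batch could be tested. A common target for all arrays fixes the trimmed mean, not the median, so a shift of the typical probe set between groups can come from the scaling. The filter at a log2 signal of 4 had been fixed in the belief that the values came from GCRMA.

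The table held 45101 probe sets for 15 arrays, and every sample column was used. A probe set took its gene from the platform annotation given with the table: 34958 had 1 gene symbol, 932 had several and 9211 had none. Only probe sets with 1 symbol were named, and 34754 of these were also found by gene identifier in the RefSeq gene table of assembly GRCm38.p6, which changed no symbol. That table also gave the order of genes along chromosomes. No 2 arrays shared more than 0.29% of their values, so none was a copy of another.

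All signals were above 0 and were log2-transformed with no pseudocount. The 64 Affymetrix control probe sets were left out of the tests. A probe set was tested if its log2 signal exceeded 4 on at least 7 of the 15 arrays, without regard to group, which left 38870 probe sets for 16627 named genes. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ratios of geometric means. For gene lists, each gene was represented by its tested probe set with the highest mean over all arrays. Of 36 lists written before the data were examined, the sex-linked genes served only as a check of sex, and the other 35 had at least 5 tested genes. They were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 35 lists. The same lists were tested with an estimated correlation and with fry. Counts of list members are given adjusted over all probe sets and adjusted over the list alone. Array-level values were compared with exact two-sided permutation tests in scipy 1.17.1 under Python 3.11.15, adjusted over 19 values. Figures were drawn with matplotlib 3.10.9.

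Genes were named by a rule fixed before the data were examined: the 10 largest increases and 10 largest decreases among probe sets past the threshold, Lmna, up to 3 members with the smallest p of each list that was shifted or held a passing member, and 1 member of a few lists of prior interest. Other members that passed adjusted over their list alone, or in another of their probe sets, were named after their values were seen. List genes that no single-gene probe set of the annotation names were not analysed here.

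The test was run on simulated arrays with the real means and residual SDs of the 38870 probe sets, normal and independent errors, and 50 probe sets changed by each of 4 sizes. For this comparison it called 4% of the changes of log2 0.5, 26% of those of 1, 60% of those of 2 and 96% of those of 4, with 2 false calls. In 20 simulated sets of 16627 genes, camera called a list shifted by a log2 of 1 in 20 and none of 620 unshifted lists. These simulated genes were independent, so this does not test the preset correlation.

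The alternatives planned in advance were no filter, a filter at a log2 signal of 6, centring each array on its median, quantile normalization, array weights, a trended and robust prior, the replicate number as a block, the first principal component of the residuals or the atrial mean as a covariate, a rank sum test, an unmoderated linear model, a minimum change of 1.5-fold, other ways to choose probe sets per gene, and leaving out each array. Added after seeing the data were the RNA quality and blood covariates, the fit without 4 arrays and a floor at a log2 signal of 6.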

Results

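Total RNA of 15 male mice, from whole hearts per the labels' protocols, was measured on 1-colour Affymetrix expression arrays, 1 array per mouse. The labels give 10 weeks for every sample. The design had a single factor, genotype: 8 arrays came from control mice and 7 from mice heterozygous for Lmna H222P. Lmna encodes lamins A and C, filament proteins of the nuclear lamina, and H222P is an amino acid substitution known from a human muscular dystrophy with heart disease. The titles number the mice within each group and say nothing of litters or batches, so p-values measure the spread between these samples. The number of arrays limits the precision, since an array signal has no count behind it. Array medians lay between 56.7 and 94.2 signal units. Across probe sets, Spearman correlations ranged from 0.834 to 0.912 between control arrays, from 0.836 to 0.889 between heterozygous arrays and from 0.813 to 0.898 between the groups. The Y-linked gene Eif2s3y had 310.7 to 776.7 units in its brighter probe set on the 15 arrays. No probe set of Xist, the X-inactivation transcript of female cells, exceeded 181.5 units on any array.

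The comparison asked which transcripts of the heart differ when 1 Lmna allele carries the substitution. The 2 largest increases were in genes of atrial muscle. Sarcolipin (Sln), a small regulator of the sarcoplasmic calcium pump, was 82.9-fold higher in heterozygous hearts, the atrial myosin light chain Myl7 25.8-fold and the atrial and embryonic light chain Myl4 7.10-fold. Sln and Myl4 each had another tested probe set that did not pass, at log2 differences of -0.94 and -0.07. The fold of Sln rests on a control geometric mean of 10.2 units, a range where array signals scatter widely, and its log2 difference of 6.37 became 7.13 without control array 6. Paip1, Ifi202b and Wdfy1 rose by 14.1-fold, 12.1-fold and 4.71-fold, over control geometric means of 20.4, 8.43 and 78.5 units, the first 2 of them weak signals too. Among the decreases were the platelet chemokine Ppbp, 3.91-fold lower, the erythroid haem synthesis enzyme Alas2, 2.58-fold lower, and the sodium channel subunit Scn4b, 2.84-fold lower. In all, 98 of 38870 probe sets passed limma's moderated test after Benjamini-Hochberg adjustment, 35 higher and 63 lower in heterozygous hearts. The 80 of them that name 1 gene stood for 77 genes, 28 higher and 49 lower. The groups did not overlap at all in 0.468% of all tested probe sets, against 0.0311% by chance for 8 against 7 arrays. At an unadjusted p under 0.05 there were 5663 probe sets, where 1944 would come by chance.

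**Figure D1:**
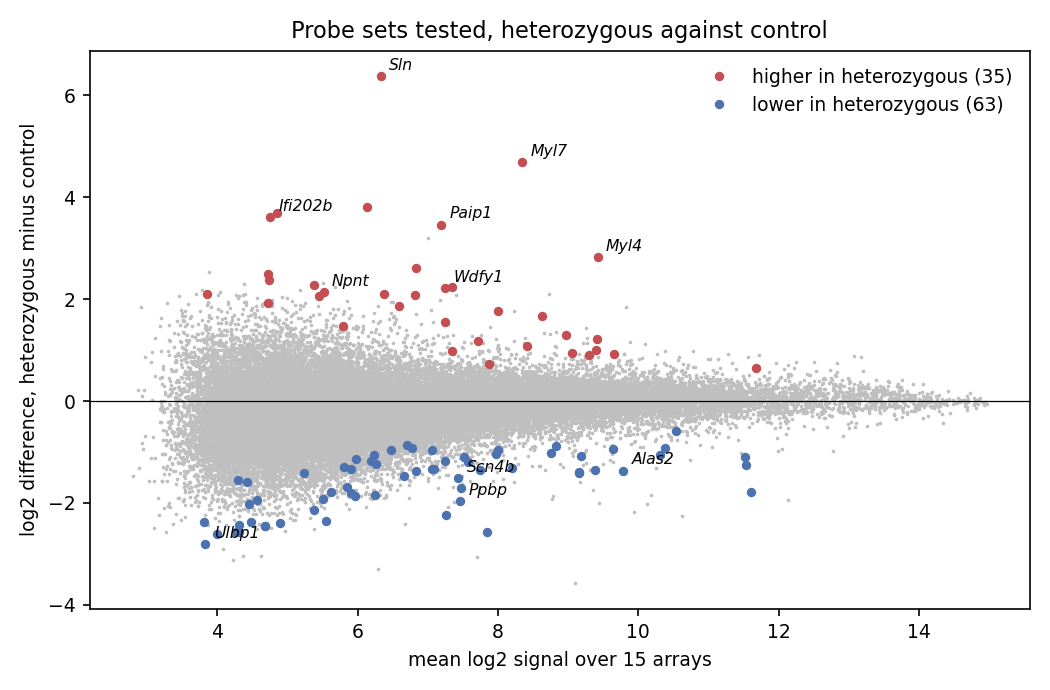
Each point is a tested probe set; the x axis is its mean log2 signal over the 15 arrays and the y axis the log2 difference, heterozygous minus control. The 35 red and 63 blue points passed the adjusted threshold, with Sln at 6.37 and Ulbp1 at -2.80 as their extremes.

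The balance of higher and lower calls depended on the scaling of the arrays. The median difference over all tested probe sets was -0.11 (log2) on the deposited scale and 0.08 after each array was centred on its median. That centring gave 56 higher and 20 lower probe sets, and quantile normalization gave 38 higher and 27 lower. A Wilcoxon rank sum test passed 0 probe sets, with a smallest adjusted p of 0.0664 and 4895 probe sets at an unadjusted p under 0.05. Its p cannot go below 0.000311 with 8 against 7 arrays, which left the 182 probe sets whose groups separate completely above the threshold. Leaving out control arrays 1 to 7 in turn gave 27, 32, 27, 24, 52, 55 and 17 probe sets, and leaving out heterozygous arrays 1, 4, 6 and 7 gave 40, 20, 54 and 150.

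The 10 genes with the largest increases were Sln, Myl7, Paip1, Ifi202b, Myl4, Tmem87a, Slc24a2, Wdfy1, Npnt and Cdc23. Mean log2 signals of Sln were 3.36 ± 2.23 (SD, n = 8) in control and 9.73 ± 1.51 (SD, n = 7) in heterozygous hearts, with limma's adjusted p = 0.0122. Those of Myl7 were 6.15 ± 1.78 and 10.84 ± 1.31, with an adjusted p of 0.0255. Those of Myl4 were 8.10 ± 0.97 and 10.93 ± 1.01, with an adjusted p of 0.0298. Control array 6 stood apart from the other controls in all 3 genes, at 406.7 units for Sln, 1212.9 for Myl7 and 1399.8 for Myl4. The other 7 controls reached at most 12.2, 120.1 and 278.2 units. For Sln these controls lay below the lowest array median, 56.7 units. How much atrial tissue each sample held was not measured, so these differences need not come from genotype. Paip1, which binds the poly(A)-binding protein, passed in 2 of 4 tested probe sets. The adjusted p of its brighter called probe set was 1.1e-05, and another probe set of Paip1 was lower in heterozygous hearts by a log2 difference of -0.84 without passing. Wdfy1, an endosomal adaptor protein, passed in 2 of 5 probe sets and its groups did not overlap. Ifi202b, an interferon-activated gene with a single tested probe set, had geometric mean signals of 8.43 and 102.3 units.

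**Figure D2:**
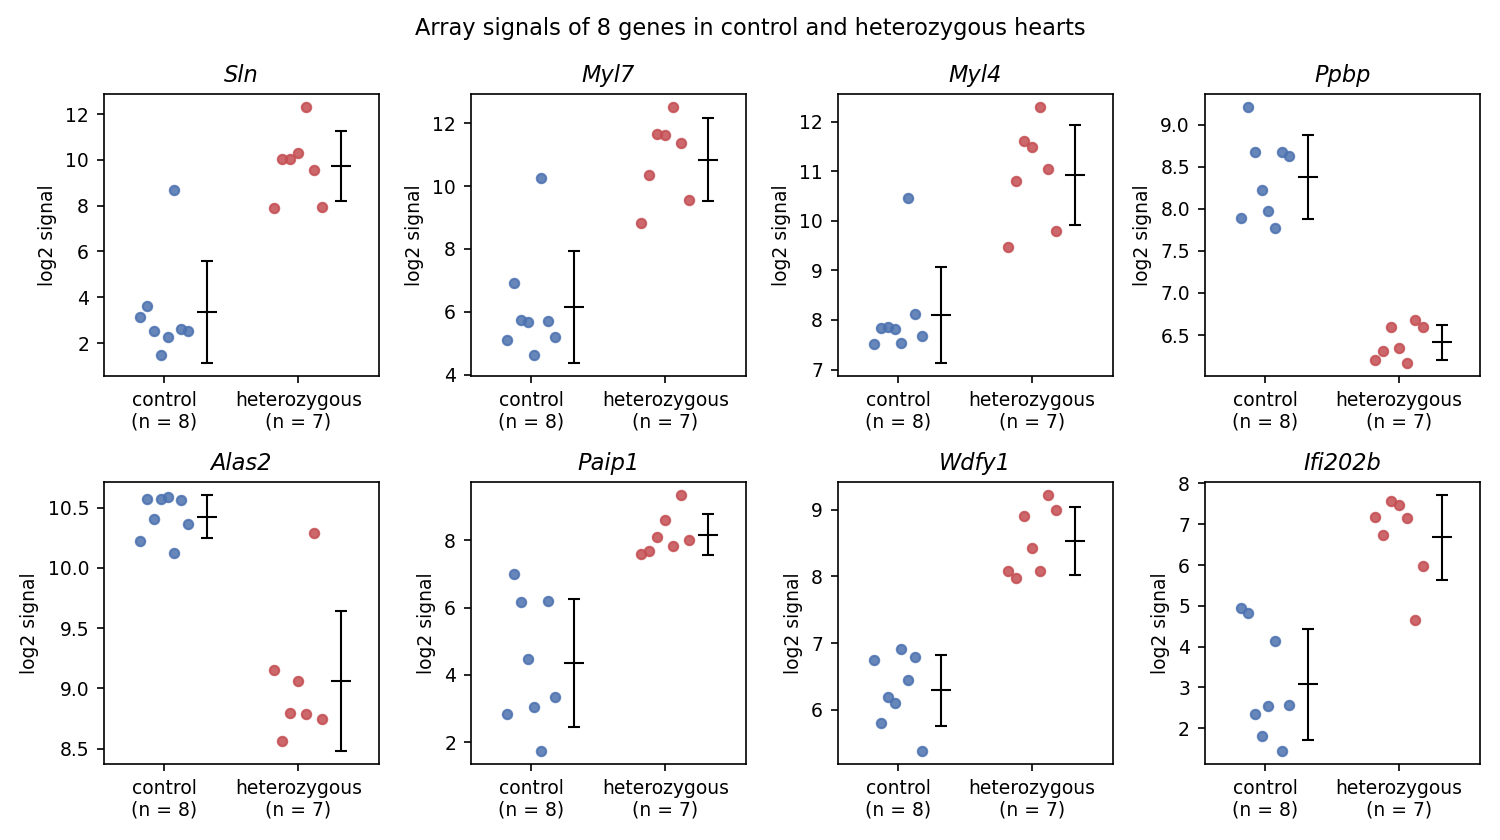
Log2 signals of 8 genes on each array, control in blue (n = 8) and heterozygous in red (n = 7), with the group mean and SD as black bars. The high control point for Sln, Myl7 and Myl4 is control array 6, and Ppbp, Paip1 and Wdfy1 separate the groups completely.

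Tmem87a was 6.09-fold higher, the potassium-dependent sodium/calcium exchanger gene Slc24a2 5.62-fold, the matrix protein gene Npnt 4.40-fold and the anaphase-promoting complex gene Cdc23 4.29-fold. Slc24a2, Npnt and Cdc23 each passed in 1 probe set while other tested probe sets of these genes did not pass. These others reached down to log2 differences of -0.54 for Slc24a2 and -1.12 for Npnt, while those of Cdc23 were above 0. The 10 genes with the largest decreases were Ulbp1, Cep135, Plaat1, Cklf, Lpar2, Kansl1l, Wdr27, Sema5a, Prrt1 and Gm26782, between 4.69-fold and 6.98-fold lower. Of these, 8 had geometric mean signals under 20 units in heterozygous hearts. Cklf passed in 1 of 7 tested probe sets, and its others reached up to a log2 difference of 0.44. All tested probe sets of Plaat1, Kansl1l, Sema5a and Prrt1 were below 0. With signals under a log2 of 6 set to 6, a choice made after seeing the data, 7 of the 10 no longer passed: the differences became -0.04 for Kansl1l and Sema5a, -0.09 for Cep135, -0.15 for Lpar2, -0.20 for Wdr27, -0.27 for Cklf and -0.65 for Prrt1. No array had Ulbp1 or Cdc23 above the floor in these probe sets, so they were not tested there. Among the increases that floor gave Ifi202b 0.87, Slc24a2 0.21 and Npnt 0.69, none passing. Plaat1, a phospholipase and acyltransferase gene, was brighter, falling from 525.3 to 88.6 units with an adjusted p of 0.0298. Gm26782 fell from 313.7 to 66.8 units with an adjusted p of 0.0273. Of the 23 named genes that passed, 12 had several tested probe sets, and in none of the 12 did every probe set pass. When each array was left out in turn, Sln, Wdfy1 and Ppbp passed in all 15 fits. In the 1 probe set followed per gene, the other 20 lost the call in some fits, with adjusted p of at most 0.101. The brighter called probe set of Paip1 was not followed. Ulbp1 and Cep135 passed in 1 of 15 fits, Npnt, Kansl1l, Sema5a and the weaker called probe set of Paip1 in 2, and Tmem87a, Lpar2 and Scn4b in 3.

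Lmna itself did not pass. Its signals were 574.8 units in control and 772.1 units in heterozygous hearts, a ratio of 1.34 with limma's adjusted p = 0.349, and 0 of its 5 tested probe sets passed. A point substitution leaves the transcript in place, so this level does not check the genotype labels. Among the 20 tested genes of the nuclear envelope and lamina, 0 passed over all probe sets or adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.240; adjusted p = 0.383 with an estimated correlation).

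Genes of the MAP kinase pathway, which carries growth signals to the nucleus, were examined because lamin mutations have been tied to it. None of the 25 immediate early genes passed over all probe sets. Adjusted over the list alone, 1 rose, the transcription factor Egr1, from 8.34 ± 0.26 to 9.19 ± 0.56 in log2 signal (1.80-fold). The list as a whole was not shifted (camera adjusted p = 0.819; adjusted p = 0.954 with an estimated correlation). Of 26 MAP kinase cascade components, 0 passed over all probe sets and 1 rose adjusted over the list alone, Mapk10, which encodes the kinase JNK3, at 1.81-fold. Its other tested probe sets reached down to a log2 difference of -1.29. The list adjusted p was 0.341 with camera, and the adjusted p = 0.805 with an estimated correlation. Of 29 other fits 2 called the list, the Actb covariate and the fit without 4 arrays of steep Actb ratio, both chosen after seeing the data. Of 18 ERK feedback and ERK-responsive genes, 0 passed by either adjustment. The smallest p among them was that of the phosphatase gene Dusp4, at 5.91 ± 1.07 against 4.13 ± 1.05 in control, with an adjusted p of 0.163. That list gave a camera adjusted p of 0.345, and an adjusted p = 0.558 with an estimated correlation.

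Of 35 lists fixed before the data were examined, 8 were shifted by limma's camera test. Atrial cardiomyocyte markers, fetal and stress-response cardiac genes, fibroblast markers, extracellular matrix genes, TGF-beta and BMP signalling, Wnt signalling and macrophage markers were shifted upward relative to other genes, and erythroid and blood markers downward. With an estimated correlation between genes, 2 of the 8 calls held, those of the atrial and of the blood markers. The limma test fry, which does not set a list against other genes, passed the same 2 lists. Camera at its preset correlation also called a median of 4 lists when the 15 arrays were split otherwise, as described below. Its adjusted p-values therefore do not by themselves show an effect of genotype.

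Among 19 atrial markers, Sln, Myl7 and Myl4 rose over all probe sets. Adjusted over the list alone, 6 rose and 1 fell. The risers included the natriuretic peptide Nppa (1.83-fold), the secreted protein Dkk3 (1.97-fold) and the amidating enzyme Pam (4.29-fold), and the potassium channel gene Kcna5 fell, at 0.651 of control. The list's camera adjusted p was 0.000441, and the adjusted p = 0.0402 with an estimated correlation. Its mean difference was 0.96 and its median difference 0.30 (log2). With the atrial mean of each array, taken without Nppa, as a covariate, 5 probe sets passed in place of 98, and the difference of Myl7 was 1.03. That mean includes Sln, Myl7 and Myl4 themselves, so a smaller difference of Myl7 was built in. It also differs between the groups, so this fit cannot tell how much of the other calls goes with atrial markers. Ventricular markers had a list mean of 11.49 ± 0.20 in control and 11.57 ± 0.20 in heterozygous hearts and were not shifted (camera adjusted p = 0.819; adjusted p = 0.954 with an estimated correlation).

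None of the 18 fetal and stress-response genes passed over all probe sets. Adjusted over the list alone, 7 rose and 1 fell. The smooth muscle actin Acta2 was 1.70-fold higher, the LIM protein Fhl1 1.67-fold and the slow myosin heavy chain Myh7 3.61-fold. Other tested probe sets of Acta2 lay at log2 differences of -1.55 and 0.95, and that of Fhl1 at -0.55, none passing. The skeletal actin Acta1 fell, at 0.506 of control. Myh7 reached 8570.3 and 6204.5 units on heterozygous arrays 1 and 2, while the other 5 heterozygous arrays lay between 559.5 and 1673.6 and the controls between 412 and 587.6. The list call (camera adjusted p = 0.000902) was lost with another estimate of the spread shared by its genes (adjusted p = 0.253 with an estimated correlation). Of 25 sarcomere genes 0 passed by either adjustment. The smallest p was that of Smyd1, at 0.702 of control with an adjusted p of 0.271, and the list was not shifted (camera adjusted p = 0.725; adjusted p = 0.954 with an estimated correlation). Of 26 calcium handling and ion channel genes, 1 fell by either adjustment, Scn4b, from 8.14 ± 0.30 (SD, n = 8) to 6.63 ± 0.76 (SD, n = 7) with limma's adjusted p = 0.0412. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, stood at 0.741 of control without passing. Scn4b no longer passed after centring on the median (adjusted p = 0.0736) or quantile normalization (adjusted p = 0.0679).

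Blood transcripts were lower in heterozygous hearts. Of 8 erythroid and blood markers, Ppbp and Alas2 fell over all probe sets, and 4 fell adjusted over the list alone. These 4 were Ppbp, Alas2, the red cell anion exchanger Slc4a1 (0.403 of control) and the red cell enzyme Bpgm (0.596 of control). Slc4a1 also passed over all probe sets in another of its probe sets. Ppbp measured 8.38 ± 0.50 (SD, n = 8) in control and 6.41 ± 0.21 (SD, n = 7) in heterozygous hearts, with limma's adjusted p = 0.00117. Alas2 measured 10.43 ± 0.18 and 9.06 ± 0.58, with an adjusted p of 0.0255 that rose to 0.0728 after centring on the median. The platelet factor Pf4 did not pass, at 10.43 in control and 10.26 in heterozygous hearts (adjusted p = 0.776). The list's camera adjusted p was 6.83e-05, and the adjusted p = 0.0122 with an estimated correlation.

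None of the 16 fibroblast markers or 35 extracellular matrix genes passed over all probe sets. Adjusted over the list alone, 3 of 16 fibroblast markers rose: the matrix proteoglycan Dcn (1.84-fold), the growth factor receptor Pdgfra (1.57-fold) and the collagen gene Col1a2 (1.57-fold). The other tested probe set of Dcn lay at a log2 difference of -0.47, and those of Pdgfra reached down to -0.38, while all those of Col1a2 were above 0. The list call had a camera adjusted p of 9.92e-05, and an adjusted p = 0.115 with an estimated correlation. Of 35 extracellular matrix genes, 1 rose adjusted over the list alone, Dcn. The growth factor Ccn2 stood at 1.98-fold with an adjusted p of 0.218. That list's camera adjusted p was 0.00715, and the adjusted p = 0.558 with an estimated correlation. It lost the call without heterozygous array 1 (adjusted p = 0.0690), without heterozygous array 6 (adjusted p = 0.113) and after quantile normalization (adjusted p = 0.0778).

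Of 31 TGF-beta and BMP signalling genes, 0 passed over all probe sets and 2 rose adjusted over the list alone, the receptor gene Tgfbr2 (1.66-fold) and Id2 (2.10-fold), an inhibitor of helix-loop-helix factors. The secreted matrix protein gene Tgfbi stood at 0.683 of control without passing. Other tested probe sets of Tgfbr2 reached down to a log2 difference of -0.48, and those of Tgfbi up to 1.05. The camera adjusted p was 0.00321, and the adjusted p = 0.132 with an estimated correlation. The call was also lost with the mean of probe sets per gene (adjusted p = 0.0576). Of 33 Wnt signalling genes, 0 passed over all probe sets in the probe set that stood for the gene. Tcf7l1 rose over all probe sets in another of its probe sets. Adjusted over the list alone 2 rose, Wif1 (3.85-fold) and Dkk3, and Frzb stood at 1.58-fold without passing. Wif1 and Frzb encode secreted antagonists that bind Wnt proteins. The camera adjusted p was 0.0267, and the adjusted p = 0.0938 with an estimated correlation. Of 24 macrophage and monocyte markers, 0 passed by either adjustment. Cd68, C1qc and Ccl2 stood at 1.40-fold, 1.41-fold and 1.89-fold, with adjusted p from 0.322 to 0.390. The camera adjusted p was 0.0459, and the adjusted p = 0.783 with an estimated correlation. The macrophage call was lost without control arrays 2, 3, 5 and 6 in turn (adjusted p = 0.0840, 0.0560, 0.0564 and 0.0536) and without heterozygous arrays 1, 3 and 7 (adjusted p = 0.493, 0.106 and 0.0640). It was lost too with the log2 filter at 6 (adjusted p = 0.0891), quantile normalization (adjusted p = 0.0925), array weights (adjusted p = 0.0833) and the floor (adjusted p = 0.0546). The Wnt call was lost with the filter at 6 (adjusted p = 0.0891) and with the atrial covariate (adjusted p = 0.460).

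The other 27 lists were not shifted, with camera adjusted p from 0.0551 to 0.961. Because camera sets a list against other genes, whose typical difference was below 0, 6 lists leaned upward with means below 0: sarcomere (-0.0074), oxidative phosphorylation (-0.02), glycolysis (-0.04), p53 targets (-0.08), circadian output (-0.11) and skeletal muscle (-0.07). Ventricular markers had a mean difference of 0.08 and a median of -0.05, and MAP kinase components a mean of 0.03 and a median of -0.0021. For energy metabolism, 0 of 29 fatty acid oxidation genes and 0 of 43 oxidative phosphorylation genes passed by either adjustment. Of 21 glycolysis genes, Hk1 alone rose adjusted over the list alone. Of 27 heat shock and unfolded protein genes, the chaperone genes Hspa1a, Hspa1b and Dnaja1 fell adjusted over the list alone, to 0.346, 0.333 and 0.646 of control, and the asparagine synthetase gene Asns rose 1.79-fold. No gene passed by either adjustment in the lists of p53 targets (17 tested), autophagy and atrophy (19), cell cycle (25), circadian output (18), or corticosteroid and fasting response (15). Of 21 interferon-stimulated genes 1 fell adjusted over the list alone, Rsad2.

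Signs of RNA quality and of other tissues were compared as 19 values per array with exact two-sided permutation tests. The mean of the atrial markers was 0.96 higher in heterozygous hearts (adjusted p = 0.00591), and that of smooth muscle and pericyte markers was 0.26 higher (adjusted p = 0.0236, and 0.0506 without heterozygous array 4, 5 or 6). The mean of the erythroid and blood markers was lower, with a difference of -0.87 (exact p = 0.000311, the smallest that 8 against 7 arrays allow; adjusted p = 0.00591). With the median of each list's members in place of the mean, the blood difference passed, the adipocyte difference passed too (0.68, adjusted p = 0.00295), and the atrial difference (0.62, adjusted p = 0.0905) and the smooth muscle difference (0.15, adjusted p = 0.352) did not. The share of probe sets above a log2 signal of 4 was 82.2% ± 2.56 (SD, n = 8) in control and 79.3% ± 2.36 (SD, n = 7) in heterozygous hearts (exact permutation test, adjusted p = 0.0901). The Actb control probe sets read 0.64 ± 0.30 (log2, SD, n = 8) brighter at the 3-prime than at the 5-prime end in control and 0.91 ± 0.55 (SD, n = 7) in heterozygous hearts (exact permutation test, adjusted p = 0.325). This difference exceeded 1 on control array 6 and heterozygous arrays 2, 3 and 5. Without these 4 arrays, a choice made after seeing the data, 90 probe sets passed, 29 of them among the 98.

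**Figure D3:**
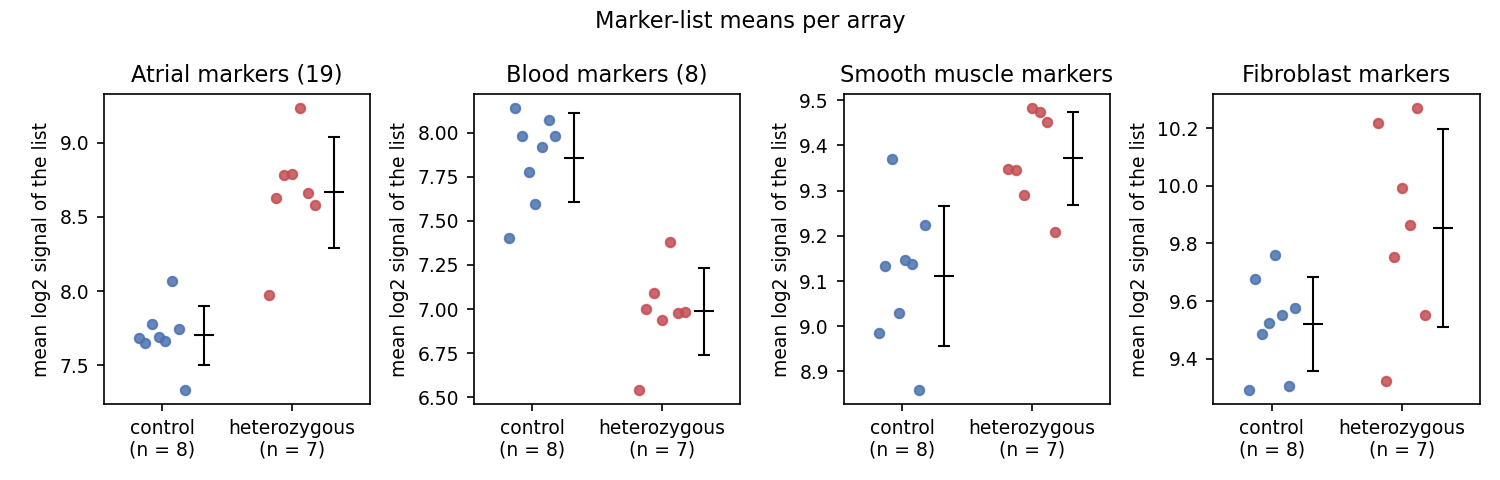
Mean log2 signal of the tested members of 4 marker lists on each array, control in blue (n = 8) and heterozygous in red (n = 7), with the group mean and SD as black bars. The atrial means averaged 7.70 and 8.66 and the blood means 7.86 and 6.99 in control and heterozygous hearts.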

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

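The tests of the atrial and blood patterns were set down before their results were seen, and those of the Paip1, Wdfy1 and Ifi202b pattern after. Over 132 group-wise looks at 66 genes and array-level values, 11 values lay far from the rest of their group, where chance would give about 6.6; they came from 5 arrays.

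Control array 6 was far above the other controls in log2 signal of Sln (8.67), Myl7 (10.24) and Myl4 (10.45), whose highest values in the other controls were 3.61, 6.91 and 8.12. This bears on the rise of atrial markers, since a control heart showed the same 3 transcripts. RNA degradation was argued against as the whole cause: with the Actb 3-prime minus 5-prime difference as a covariate, the atrial difference was 0.894 of its unadjusted size (95% bootstrap interval 0.693 to 1.09). More atrial tissue in some samples and a fetal gene programme in heterozygous hearts both stay open, as hypotheses. Among heterozygous arrays, Sln, Myl7 and Myl4 were all highest on array 5 and lowest on array 1. These genes raised the question, so their moving together decides for neither. Across 15 deviations from group means, the other 15 atrial markers showed no detectable relation to Myl7 (Pearson r = -0.026, permutation p = 0.917; Spearman rho = 0.011, permutation p = 0.976; 95% interval of r -0.814 to 0.769; r = 0.25 without control array 6 and heterozygous array 5; r = -0.596 within control and 0.621 within heterozygous arrays), and of the 19 markers 8 exceeded a log2 signal of 8 in controls and 3 belong to another list too, so a small amount of atrial tissue could leave many of them unmoved. The mean of 8 fetal genes outside the atrium differed by 0.19 (exact permutation p = 0.331; 95% bootstrap interval -0.12 to 0.54), which neither needs nor excludes such a programme.

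Alas2 on heterozygous array 6 reached 10.29, against at most 9.16 on the other heterozygous arrays, and Bpgm on heterozygous array 7 was lowest at 7.74. RNA degradation was argued against for the lower blood markers: with the Actb covariate their difference was 1.046 of its unadjusted size (95% bootstrap interval 0.951 to 1.22). Less residual blood in the heterozygous samples stays open as a hypothesis. Platelet genes were lower by a mean difference of -0.79 (95% bootstrap interval -1.12 to -0.45) and erythroid genes by -0.95 (-1.26 to -0.63), but members moved unlike each other: Pf4 by -0.18 and Hba-a1 by -0.39 without passing, against -1.97 for Ppbp and -1.37 for Alas2. Within groups the 2 means did not visibly move together (Pearson r = 0.04, permutation p = 0.889; Spearman rho = 0.20, permutation p = 0.484; 95% interval of r -0.581 to 0.560; r = 0.025 without heterozygous arrays 3 and 5), too wide an interval to decide, and a lower output of both lineages with the genotype was not tested.

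Ulbp1 was far above the other heterozygous arrays on heterozygous array 7, at 5.25 against at most 2.54. Col1a2 and Pdgfra were far below the other heterozygous arrays on heterozygous array 2, at 9.88 and 8.94. Tgfbi was far above the others on heterozygous array 7, at 9.56. Wif1 was far below the other controls on control array 2, at 2.81. Control array 2 also had the highest share of probe sets above a log2 signal of 4, at 87.65%, against at most 83.0% in the other controls.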

How the results depend on the processing

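The count of probe sets past the threshold was the least stable result: 98 (35 higher, 63 lower) became 67 with no filter (40 lower), 192 with the log2 filter at 6 (75 and 117), 76 after median centring (56 and 20), 65 after quantile normalization (27 lower), 312 with a trended and robust prior (141 and 171), 194 with the first residual principal component (60 and 134) and 5 with the atrial mean as covariate (1 and 4). The Wilcoxon test gave 0 in either direction, because its smallest p with 8 against 7 arrays leaves an adjusted p of 0.0664, and the mean of probe sets per gene gave 22 higher. Leave-one-out counts ran from 17 to 150, with 10 to 52 higher and 7 to 98 lower. Chosen after seeing the data, the fit without 4 arrays of a steep Actb ratio gave 23 higher, a floor at log2 6 gave 287 (120 and 167), and the blood mean, or the atrial, blood and Actb covariates together, gave 0. The cause was not tested. The atrial and blood means differ between the groups, so those fits cannot separate genotype from these covariates. Under the blood covariate some log2 differences grew without passing, as that of Sln from 6.37 to 8.98. Others shrank, as that of Cklf from -2.45 to -1.515. Nothing showed that like numbers in both groups pair the mice, though these values cannot exclude it. Correlations of like-numbered deviations ran from -0.06 to 0.06, and 1 of 7 heterozygous arrays correlated best with its own number. With a replicate block, a fit without control array 8, 1 probe set passed (1 higher, 0 lower) and the Wnt list lost its call (camera adjusted p = 0.0543). Of the 8 shifted lists 2 held with an estimated correlation and 2 with fry. The blood covariate gave 3 lists, 1 of the 8 (atrial) with sarcomere and glycolysis, and the 3 covariates gave 7, of which 3 were among the 8 (fetal, TGF-beta, macrophage). Leave-one-out fits gave 6 to 12 lists, with 6 to 8 of the 8 among them. Under the blood covariate the shift turned to -0.023 for matrix, -0.33 for macrophage and 0.037 for blood lists, and the log2 difference to -0.27 for Lmna, -0.050 for C1qc and -0.46 for Ccl2; under the 3 covariates it turned to 0.14 for the blood list, -0.24 for Wdfy1, -0.033 for Acta2, -0.037 for Ccl2 and 0.039 for Bpgm. With list medians, the differences of ventricular and of cartilage markers turned to -0.027 and -0.17. The 3 array-level values that passed ran from 2 to 6 over leave-one-out fits, with 5 without heterozygous array 7 and 6 without control array 8. The skeletal muscle difference of -0.07 ran from -0.21 to 0.038, turning to 0.017 without control array 6 and 0.038 without heterozygous array 6. No planned setting turned the direction of a shifted list or of a gene named by the rule fixed in advance. Other genes named here were not followed through the settings. Under the planned settings apart from leave-one-out fits, 326 gene values kept their side of the threshold, 69 lost a call and 16 gained one; under those chosen after seeing the data 144 kept it, 76 lost a call, 6 gained one and 7 turned direction. Weak signals limit what the arrays can show, since 42.1% of tested probe sets had means under log2 6.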

Other observations

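The tests of linkage below were chosen after the list of genes had been seen, and the splits of the arrays were planned. Genes in this part were chosen after their values were seen. Among markers of other tissues, no list given here was shifted with all arrays and the fixed settings, but of 29 other fits 9 called the lung list, 8 the endothelial, 5 the smooth muscle and 3 the adipocyte list. Of 14 smooth muscle and pericyte markers, Acta2, Tagln (1.85-fold), Myh11 (1.52-fold) and Cnn1 (2.66-fold), which belong to the contractile apparatus of vessel walls, rose adjusted over the list alone, and the pericyte gene Rgs5 fell to 0.743 of control (camera adjusted p = 0.0796; adjusted p = 0.296 with an estimated correlation). Of 11 cartilage and valve markers, the matrix genes Comp (2.46-fold), Chad (2.65-fold) and Prg4 (3.40-fold) rose adjusted over the list alone, while the list's mean difference was 0.13 and its median difference -0.45 (camera adjusted p = 0.286; adjusted p = 0.420 with an estimated correlation). Of 17 endothelial markers, the growth factor receptor genes Kdr (1.46-fold) and Flt1 (1.33-fold) rose and the lymphatic regulator Prox1 fell, to 0.647 of control, adjusted over the list alone (camera adjusted p = 0.101; adjusted p = 0.479 with an estimated correlation).

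Of 11 lung and airway markers 1 fell adjusted over the list alone, Slc34a2, and the list mean was 5.88 ± 0.34 (SD, n = 8) in control and 5.16 ± 0.55 (SD, n = 7) in heterozygous hearts (exact permutation test, adjusted p = 0.0517). That adjusted p was 0.0443 without control array 4, 0.0277 without control array 8, 0.0475 without heterozygous array 3 and 0.0158 without heterozygous array 7. The other leave-one-out fits left it above the threshold. Of 11 neutrophil and acute-phase markers Lcn2 rose 3.31-fold and Mmp8 fell to 0.593 of control adjusted over the list alone, and of 12 nerve markers Cnp rose 1.53-fold. By either adjustment 0 of 20 skeletal muscle, 0 of 14 adipocyte (median of members 0.68 higher, adjusted p = 0.00295), 0 of 15 lymphocyte and 0 of 13 mesothelial markers passed. Outside the lists, 2 genes known from platelets fell over all probe sets: Tubb1, the platelet tubulin, had a log2 difference of -1.46 (limma adjusted p = 0.0108) and Clec1b, a platelet receptor, one of -1.33 (adjusted p = 0.0255), while Pf4 did not pass.

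Paip1 and Wdfy1 separated the groups completely and Ifi202b, weak in controls, nearly so. Complete separation held in 67 of the 98 called probe sets, so it does not set these genes apart. A hypothesis is that they mark stretches of the genome that come from different mouse strains in the 2 groups. Stretches linked to the targeted Lmna locus were argued against, because 0 of the 3 genes lay among the 200 tested genes nearest to Lmna in the gene order of GRCm38.p6, and all 3 lie on other chromosomes than Lmna. Linked stretches elsewhere may contribute, but the tests leave this open: 35 pairs of the 77 called genes lay within 50 tested genes of each other, against a median of 17 when the calls were dealt to random genes 10000 times (permutation p = 0.0006), so called genes as a whole lay close together. Ifi202b had Pex19, Igsf8 and Dusp23, and Paip1 had Tmem267, as called neighbours, while Wdfy1 had 0, and these 4 were ordinary beside 3 other called genes (mean 2.69, permutation p = 0.305). Neighbouring genes can also share regulation, which was not tested. A variant under single probes stays open too: 70% of the 10 tested probe sets of the 3 genes were higher at an unadjusted p under 0.05, but 5 of these 7 are the called ones by which the genes were chosen, so this share decides nothing.

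Chance was argued against for the number of probe sets. Of 100 splits of the 15 arrays into 8 and 7, 1 gave as many as the real 98, the real split itself, and the highest other gave 2. The splits cannot tell genotype from a batch or litter that differs between the groups. Chance cannot be excluded for the number of shifted lists: 15 of the 100 splits, the real one included, gave at least the real 8. The splits other than the real one gave a median of 4 lists, and 92 of them gave at least 1. The highest other gave 12 but had 1 heterozygous array in its group of 7, so it largely repeated the genotype contrast. Some of the other splits also held the genotypes unevenly. A split with 4 heterozygous arrays in its group of 7 gave 11 lists. Camera at its preset correlation thus also called many lists where the groups mixed the genotypes.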
